A study of Rana dybowskii with 27 samples.

How the data were processed

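Back skin, liver and oviduct of the brown frog Rana dybowskii were sequenced from animals of 3 colour morphs, red, black and white, with 3 biological replicates per morph and tissue in the series design (27 libraries in 9 groups). Per the labels, total RNA was extracted with TRIzol, libraries were made with a VAHTS Universal V6 kit and reads of 150 bp were taken from both ends on a NovaSeq 6000. The submitters' processing notes name Trimmomatic for trimming, Bowtie2 for alignment and DESeq2 for differential expression, each without a version. The assembler and the program that produced the counts are not given in the sources used here, although the transcript identifiers follow the Trinity scheme. Sex, age, season and place of capture of the animals are not given in the sources used here. An S-number suffix on the columns of skin black 1 and 2, oviduct black 1 and oviduct red 1 is not explained there either. In skin only black libraries carry this suffix.

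The deposited values were an expected count table for 92123 assembled transcripts and an FPKM table for 92131, both computed by the authors, with all 27 value columns matched to libraries through the file headers. Counts were not whole numbers for 70.3% of transcripts, so they were taken as estimated counts and rounded. The transcript length implied by count and FPKM varied across libraries by a median of 5.0% (coefficient of variation), so both tables describe the same quantity. The 8 transcripts held by the FPKM table alone reached at most 9.02e-11 FPKM, below the 0.00117 FPKM that 3 counts would give. Sequence reads were not analysed here, and no genome was used, so no genomic positions are given. Annotation by NR, Swiss-Prot, KEGG, KOG, eggNOG, GO and Pfam came with the file. A gene symbol was read from it for 22305 transcripts (24.2%), giving 13076 symbols that held 68.6% to 80.9% of the counts of a library. An NR hit was present for 38063 transcripts and a Swiss-Prot hit for 24272.

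Before the data were examined, the comparisons, the alternatives, the gene lists and the rule for named genes were fixed. Each tissue was fitted alone, with 3 morphs, for the 9 pairs of morphs and for any difference among morphs. All 27 libraries were fitted together for the 3 tissue pairs, each averaged over morphs, and for the 3 tests of whether a pair of morphs differed by tissue. Transcripts were filtered with filterByExpr defaults, scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 (legacy form), and transcripts with a Benjamini-Hochberg adjusted p under 0.05 passed. Genes were also analysed as sums over transcripts with the same symbol, and all CPM values of named genes are TMM-scaled and relative to the counts on named transcripts. These were scaled within a tissue for the morph comparisons and over all 27 libraries for tissue comparisons, so a gene can have slightly different CPM in either place. Fold changes are log2 with a standard error (SE) from the F test, and CPM are means with a standard deviation (SD).

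A total of 30 gene lists were written from general knowledge, with 677 symbols besides 18 names of skin peptides. Of these symbols 600 were found, and the peptide names matched 24 transcripts. The agouti signalling gene was searched for under its usual names and was not matched. Each list was tested with camera in limma 3.58.1 on symbol sums with its preset correlation of 0.01 between genes, and again with the correlation estimated from the data, and p-values were adjusted over the lists of a comparison. The planned fry test of limma was also run. Its p-values were not adjusted over lists, and only those of ribosome genes in skin are given here. Lists of at least 3 members were tested. The rule for named genes took, for each pair of morphs, up to 4 symbols per list past the threshold, the 5 named transcripts with the largest change in each direction among those that passed without overlap, and up to 5 that passed in 3 tissues, and these parts named no gene because none passed. It also took a fixed set of 15 pigment genes in skin whatever their p and, for the tissue comparisons, the 3 symbols of highest CPM in each of the melanin, keratinocyte, hepatocyte and oviduct secretion lists. The 132 other gene examples, up to 3 per list with the smallest p-values and at least 5 CPM in a morph, were chosen after values were seen. Some of these genes are not reported here.

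A planted-difference test was run for red against black in each tissue, with counts simulated at the fitted spread and 50 transcripts or symbols changed at each fold size. With transcripts, 0 of 50 were recovered by edgeR at 2-, 4-, 8- or 16-fold in each tissue, so a count of 0 transcripts does not show that morphs are alike. With symbol sums, edgeR recovered 2, 25, 44 and 48 of 50 in skin, 1, 23, 39 and 47 in liver, and 0, 1, 7 and 30 in oviduct at these fold sizes. In the same simulation, 250 of 333 DESeq2 calls in skin, 232 of 306 in liver and 211 of 247 in oviduct fell on unchanged transcripts. At these fold sizes DESeq2 recovered 0, 9, 32 and 42 of 50 transcripts in skin. It recovered 2, 9, 21 and 42 in liver and 0, 6, 6 and 24 in oviduct. With symbol sums, 42 of 182, 34 of 169 and 50 of 139 DESeq2 calls fell on unchanged symbols. These shares depend on how many changes were planted. A list of 30 symbols shifted 2-fold gave camera p = 2.81e-27, 6.12e-18 and 1.12e-12 in skin, liver and oviduct with the preset correlation, and p = 1.75e-05, 6.44e-05 and 0.00174 with an estimated correlation. The simulated genes varied independently of each other. Genes of a real list can move together, as ribosome genes did in skin (estimated correlation 0.594 for red over black). The simulation therefore does not show how either form of camera performs on such lists.

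The replicate numbers were checked for pairing through the correlation of residuals from group means. Libraries with the same morph and number in different tissues correlated above 0.1 in 27 of 27 pairs (median 0.53, lowest 0.23), while different numbers had a median of -0.28, so a number marks an animal within a morph. Across morphs within a tissue the median was -0.01 with 2 of 27 pairs above 0.1, so numbers were not treated as pairs between morphs. Within a group, log2 CPM correlated at 0.738 to 0.841 outside the oviduct. The library labelled black oviduct 3 correlated at 0.508 and 0.468 with its replicates. Oviduct white 1 correlated at 0.647 and 0.649 with oviduct white 2 and 3, which correlated at 0.841 with each other. Chi-square per degree of freedom between replicates was 66.0 to 296, so no 2 replicates of a group were copies.

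RLE and TMM scaling differed by at most 0.04 in the median log2 fold change of all genes. Total counts in place of TMM moved that median for red over black, red over white and black over white by -0.21, 0.04 and 0.25 in skin, by -0.15, 0.33 and 0.47 in liver, and by 0.10, 0.70 and 0.60 in oviduct. Fold changes here are relative to TMM. The newer quasi-likelihood form of edgeR and a fit without oviduct red 1 and oviduct black 3 were added after the data were seen, and gave 0 transcripts, the former in each morph comparison and the latter in each within oviduct. List medians with total counts in place of TMM were also added then. Other tools were DESeq2 1.42.0, limma-voom and limma-trend in R 4.3.3, with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.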

Results

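The libraries held 12647783 to 25629386 estimated counts, with oviduct red 1 the lowest and skin red 3 next at 21503494. Mean depth (M counts) was 24.62 ± 0.76 (SD, n = 3) in black, 23.49 ± 1.43 in red and 23.53 ± 1.11 in white liver. It was 24.62 ± 0.19, 23.75 ± 1.95 and 23.86 ± 1.19 in skin, and 23.28 ± 1.26, 20.51 ± 6.82 and 24.49 ± 1.36 in oviduct. All p-values rest on what the series design gives as biological replicates, 3 per morph and tissue. Rana was the genus of the NR hit for 20783 assembled transcripts.

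The tissues differed in genes of their main cell types. KRT5, a basal keratin of stratified epithelium, averaged 14500 ± 4310 CPM in skin (SD, n = 9 per tissue), 0.177 ± 0.232 in liver and 30.8 ± 67.4 in oviduct (edgeR adjusted p = 1.34e-06 and 4.43e-05 against skin). KRT12 had 1520 ± 704 CPM in skin and 0.0752 ± 0.0818 in liver. DSP, which anchors keratin at desmosomes, was higher in skin than in liver by 5.32 ± 0.37 log2 (SE, edgeR adjusted p = 4.65e-10) and than in oviduct by 2.78 ± 0.33 (edgeR adjusted p = 1.73e-06). In liver, ALB, the main plasma carrier protein, reached 87000 ± 48000 CPM against 105 ± 225 in skin (log2 -10.45 ± 1.28 for skin over liver, edgeR adjusted p = 7.72e-07). The clotting genes FGA and FGB had 37100 ± 11400 and 28000 ± 8270 CPM in liver. In oviduct, AGR2, a disulfide isomerase needed to fold mucins, had 15500 ± 31900 CPM against 10.7 ± 3.02 in liver (log2 -7.23 ± 0.91 for liver over oviduct, edgeR adjusted p = 1.35e-06). Oviduct white 2 and 3 carried that mean, with 47200 and 89900 CPM against at most 1190 in the other oviduct libraries, and leaving out any 1 library gave log2 -7.42 to -6.40 with the lowest fold without oviduct black 1. The mucus genes FCGBP and MUC2 were higher in oviduct than in liver by 7.39 ± 1.09 and 9.15 ± 1.24 log2 (edgeR adjusted p = 1.01e-05 and 3.17e-06). PMEL, the fibril protein of melanosomes, had 207 ± 146 CPM in skin, 2.76 ± 7.69 in liver and 40.7 ± 119 in oviduct (edgeR adjusted p = 0.000153 for skin against liver and 0.00178 for skin against oviduct). Single libraries made up most of the low means, with 23.3 CPM in liver red 1 against at most 0.679 in the other livers and 357 in oviduct black 3 against at most 8.77 in the other oviducts, and without them the log2 values of 7.80 and 5.74 became 11.25 and 8.97. TYR, which starts melanin synthesis, had 1550 ± 1040 CPM in skin, 120 ± 85.4 in liver and 1550 ± 2280 in oviduct, and passed between skin and liver (log2 3.77 ± 0.63, edgeR adjusted p = 4.71e-05) but not between skin and oviduct unless oviduct red 2 was left out (0.0216).

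The gene lists tied to a tissue gave these counts with edgeR. All 30 complement and acute phase genes and all 18 hepatocyte genes were higher in liver than in skin, and all of both were higher in liver than in oviduct. Melanin genes were higher in skin than in liver for 22 of 33 and lower for 1 (24 passed adjusted over the list alone), and higher in skin than in oviduct for 16 and lower for 3, with 14 not past (20 over the list alone). Keratinocyte genes were higher in skin for 22 of 25 against liver and 21 of 25 against oviduct, where the other 4 were lower (23 and 25 passed adjusted over the list alone). Antimicrobial and other peptides of skin glands were higher in skin than in oviduct for 14 of 17 (15 over the list alone). They were higher in skin than in liver for 10 of 17 and lower for 1 (11 over the list alone). Ciliary genes were higher in oviduct than in skin for 22 of 22 and than in liver for 21 of 22, the same over the list alone. Oviduct secretion genes were higher in oviduct than in liver for 13 of 17 and lower for 1 (14 over the list alone), and higher in oviduct than in skin for 7 of 17 and lower for 1, with 9 not past (9 over the list alone). Pteridine genes were higher in liver than in oviduct for 10 of 12 (11 over the list alone), higher in liver than in skin for 6 and lower for 2 (10 over the list alone), and higher in skin than in oviduct for 7 (7 over the list alone). In all, edgeR passed 13932 of 76309 transcripts between skin and liver (8106 higher in skin), 11446 between skin and oviduct (6419 higher in skin) and 18323 between liver and oviduct (7914 higher in liver). With symbol sums it passed 4077, 4515 and 5804 of 12516.

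On average, red back skin carried more transcript of ribosomal protein genes and of several pigment cell genes than black back skin, and less of complement and interferon response genes. Here and below, example genes outside the fixed pigment set were chosen after values were seen. RPL23 averaged 3090 ± 532 CPM in red and 1640 ± 277 CPM in black skin (SD, n = 3 per morph), and RPL19 3560 ± 684 and 1980 ± 99.1, both parts of the cytosolic ribosome. SLC45A2, a melanosome transporter, had 16.6 ± 5.68 in red and 6.89 ± 1.58 in black, RAB38, which carries melanin enzymes to melanosomes, 9.53 ± 3.54 and 3.42 ± 1.02, and TRPM1, an ion channel of melanocytes, 15.5 ± 4.68 and 7.34 ± 0.501. GCH1, the entry enzyme of pteridine synthesis, had 113 ± 36.6 and 13.5 ± 8.15, and XDH, a pteridine and purine oxidase, 36.0 ± 18.1 and 9.14 ± 4.67. TYR went the other way, with 1160 ± 351 CPM in red and 2870 ± 1720 in black skin. The haem scavenger HPX had 29.6 ± 12.9 in red and 132 ± 67.6 in black skin, TLR2, a receptor for bacterial lipoprotein, 92.3 ± 3.88 and 141 ± 8.96, and IFIH1, a sensor of viral RNA, 25.9 ± 11.4 and 64.5 ± 38.8. GAP43, a nerve growth protein, had 25.3 ± 15.5 and 7.98 ± 3.81.

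As lists, ribosome genes were higher in red skin (median log2 0.72 over 34 genes, camera adjusted p = 1.92e-32, but adjusted p = 0.361 with an estimated correlation). In 33 of them all red libraries lay above all black libraries, where chance gives 10% of genes over both directions together. The ribosome genes move together (estimated correlation 0.594), so these are not 33 separate observations. Complement and interferon genes were lower in red skin (medians -1.69 and -0.96 over 26 genes each, camera adjusted p = 2.72e-05 for both, but adjusted p = 0.513 for both with an estimated correlation). Hepatocyte markers moved with them in the same skin libraries, at a median of -3.04 with 12 of 15 lower in red (camera adjusted p = 0.0885, and 0.000263 without skin black 1), and ALB had 850 CPM in skin black 2 against at most 73.4 in the other skins. Smooth muscle markers had a median of 1.01 over 10 (camera adjusted p = 0.0212, but adjusted p = 0.673 with an estimated correlation), lost without skin black 1 (0.169) or skin red 3 (0.372). Erythrocyte genes had 1.18 over 11 with 10 higher (camera adjusted p = 0.0465, but adjusted p = 0.673 with an estimated correlation), lost without skin black 1 (0.0793), skin black 2 (0.373) or skin red 3 (0.601). Skeletal muscle markers had a median of 1.47 with 11 of 13 higher, while camera placed the list downward (adjusted p = 0.995), and the median was -5.68 without skin red 3. Nerve and glia genes were higher (median 1.23 over 9, camera adjusted p = 0.00177, but adjusted p = 0.450 with an estimated correlation), as were melanin genes (median 0.49 over 32, camera adjusted p = 0.00195, but adjusted p = 0.361 with an estimated correlation). Pteridine genes had a median of 0.77 over 12 (camera adjusted p = 0.0475, but adjusted p = 0.527 with an estimated correlation), and this call was lost without skin black 1 (0.291), skin black 3 (0.104) or skin red 2 (0.229). Medians moved by over 1.5 times for complement and hepatocyte genes without skin black 2 (-0.77 and -0.50), interferon genes without skin black 1 (-0.56) and nerve and glia genes without skin red 2 (0.75), and for melanin genes with total counts in place of TMM (0.27). Carotenoid genes had a median of 0.08 (camera adjusted p = 0.208). Purine and iridophore genes had a median of -0.13 while camera placed the list upward (adjusted p = 0.492). Adjusted over the list alone, 33 of 34 ribosome, 3 of 32 melanin, 2 of 9 nerve and glia and 1 of 14 carotenoid genes passed, against 0 over all symbols.

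No single pigment gene passed between red and black skin with edgeR. Values were TYR -1.30 ± 0.61 log2 (adjusted p = 0.499), PMEL 1.40 ± 0.47 (0.436), TYRP1 1.09 ± 0.45 (0.476), SLC45A2 1.27 ± 0.31 (0.391), GCH1 3.07 ± 0.89 (0.409) and XDH 1.98 ± 0.72 (0.448). PNP, of purine recycling, had -1.98 ± 0.85 log2 (edgeR adjusted p = 0.477), and skin black 3 carried this, since the log2 value without it was 0.0029. DCT had 1.61 ± 1.35, OCA2 1.15 ± 0.68, MC1R 0.76, KIT 0.47, SCARB1 -0.82 ± 0.37, MITF 0.05 and BCO2 0.01 ± 0.23. These were smaller without single libraries, with DCT at 0.60 without skin red 1, OCA2 and TYRP1 at 0.49 and 0.70 without skin red 2 and SCARB1 at -0.30 without skin black 3. With DESeq2, GCH1 passed (adjusted p = 0.0184), as did SLC45A2 and RAB38 (0.0239 for both) and TRPM1 (0.0261). Over transcripts edgeR passed 0 of 54612, with 3155 at unadjusted p under 0.05, and limma-voom also passed 0 while limma-trend on FPKM passed up to 3 and DESeq2 938. Without skin white 2, edgeR passed 1 transcript, of RPL15. With symbol sums edgeR passed 0 of 11587, with 1186 at unadjusted p under 0.05. At 11.9% of transcripts the 2 morphs did not overlap, where chance gives 10%. Of the 30 lists, camera passed 13. At least as many passed in 4 of 10 splits of the same libraries, the real one included.

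**Figure D1:**
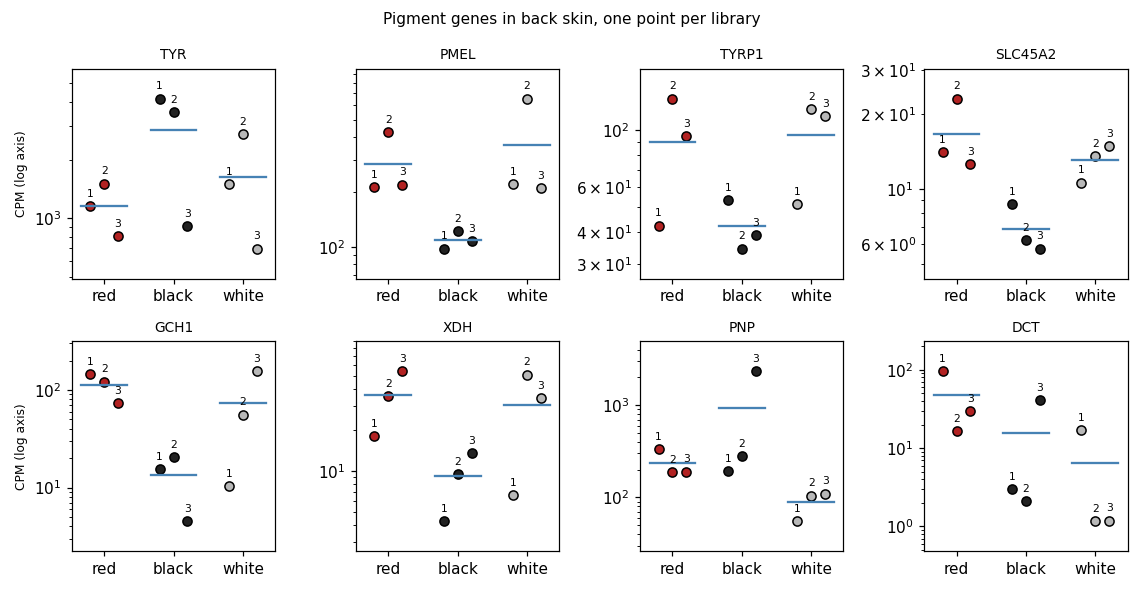
Pigment genes in back skin, with morph on the horizontal axis and CPM (TMM-scaled within skin, log axis) on the vertical axis. Each point is a library numbered by replicate, and the blue line is the mean of 3.

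On average, red skin had more transcript of immediate early response genes and less of cholesterol synthesis genes than white skin. EGR1, a transcription factor induced within minutes of a stimulus, had 326 ± 83.5 CPM in red and 173 ± 12.2 in white skin (SD, n = 3 per morph), and IER2 240 ± 29.2 and 142 ± 13.5. The sterol enzymes CYP51A1, LSS and MSMO1 had 8.06 ± 1.46, 4.78 ± 1.68 and 11.4 ± 6.68 in red and 25.5 ± 7.25, 14.4 ± 3.02 and 36.6 ± 14.6 in white skin. LOX, which crosslinks collagen, had 69.8 ± 17.5 in red and 197 ± 102 in white, and COL12A1 357 ± 146 and 848 ± 692. The inflammatory cytokine IL1B had 36.6 ± 9.07 in red and 11.1 ± 6.55 in white, the antiviral enzyme RSAD2 8.28 ± 6.34 and 1.95 ± 1.29, and the red cell membrane protein EPB42 10.2 ± 7.86 and 3.01 ± 1.86. Among pigment genes PMEL had 287 ± 121 in red and 362 ± 254 in white skin, TYRP1 89.9 ± 45.4 and 95.7 ± 38.4, GCH1 113 ± 36.6 and 73.9 ± 74.1.

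Immediate early genes were higher in red skin as a list (median log2 0.72 over 16, camera adjusted p = 7.2e-06, but adjusted p = 0.677 with an estimated correlation), and cholesterol and bile genes were lower (median -0.65 over 23, camera adjusted p = 4.14e-05, but adjusted p = 0.677 with an estimated correlation). Both lists went the same way in red against black skin. Their medians there were 0.4 and -0.87 (camera adjusted p = 0.0109 and 0.00385, but adjusted p = 0.668 and 0.513 with an estimated correlation). Collagen genes had a median of -1.05 over 21 (camera adjusted p = 0.000182, but adjusted p = 0.761 with an estimated correlation), and the call was lost without skin red 1 (0.124) or skin white 2 (0.346). Interferon genes had 0.47 over 26 (camera adjusted p = 0.000833, but adjusted p = 0.677 with an estimated correlation), lost without skin red 2 (0.125) or skin white 2 (0.679). Erythrocyte genes had 1.05 over 11 (camera adjusted p = 0.0029, but adjusted p = 0.677 with an estimated correlation), lost without skin red 3 (0.562) or skin white 1 (0.219). Ciliary genes had -0.97 over 11 (camera adjusted p = 0.0448, but adjusted p = 0.677 with an estimated correlation), lost without skin black 1 (0.238), skin black 2 (0.221), skin black 3 (0.239), skin red 1 (0.442), skin red 2 (0.149), skin red 3 (0.0581), skin white 2 (0.789) or skin white 3 (0.106). The interferon median was 0.84 without skin white 1. Melanin genes had 0.07 (camera adjusted p = 0.115), and the list passed without skin red 3 (0.0138) or skin white 2 (0.0116). Pteridine genes had -0.17 while camera placed them upward (adjusted p = 0.692), and passed without skin white 3 (0.0271). Carotenoid genes had 0.06 (camera adjusted p = 0.656), and purine genes -0.04 with an upward placement (camera adjusted p = 0.978). Within lists, 0 genes of any list named here passed adjusted over the list alone, as over all symbols.

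For pigment genes the values were DCT 2.88 ± 1.42 log2 (edgeR adjusted p = 1, as for each gene here), PNP 1.40, GCH1 0.61, SLC45A2 0.35, XDH 0.23, TYR -0.50 ± 0.60 and MC1R -0.52. Of 54612 transcripts edgeR passed 0, with 2058 at unadjusted p under 0.05, and limma-voom passed 0 while DESeq2 passed 400. For symbol sums the edgeR count was 0 of 11587, with 430 at unadjusted p under 0.05. The 2 morphs did not overlap at 8.71% of transcripts (chance 10%). Camera passed 7 of 30 lists, and at least as many in 7 of 10 splits of the same libraries, the real one included.

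On average, black skin had less ribosomal protein and collagen transcript than white skin and more complement and interferon response transcript. RPL14 had 1520 ± 152 CPM in black and 3230 ± 650 in white skin (SD, n = 3 per morph), and RPL18 1560 ± 172 and 2960 ± 398. ELN, the protein of elastic fibres, had 40.7 ± 13.0 in black and 167 ± 112 in white, and LUM, a collagen-binding proteoglycan, 165 ± 141 and 962 ± 649. HPX had 132 ± 67.6 in black and 7.90 ± 4.01 in white skin, the complement genes C2 and C3 109 ± 51.9 and 31 ± 17.5 against 19.6 ± 11.6 and 6.47 ± 4.55. STAT2, which relays interferon signals, had 82.9 ± 30.3 and 25.5 ± 9.12, and TLR2 141 ± 8.96 and 74.3 ± 10.0. GAP43 had 7.98 ± 3.81 and 29.0 ± 16.3. Among pigment genes, PMEL had 109 ± 12.1 in black and 362 ± 254 in white skin, GCH1 13.5 ± 8.15 and 73.9 ± 74.1, XDH 9.14 ± 4.67 and 30.8 ± 22.5, and PNP 935 ± 1210 and 89.8 ± 30.3.

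As a list, ribosome genes were lower in black skin (median log2 -0.80 over 34, camera adjusted p = 4.72e-31, but adjusted p = 0.670 with an estimated correlation), and in all 34 the white libraries lay above the black (chance 10% over both directions together). At an estimated correlation of 0.594 these are not 34 separate observations. Interferon genes were higher (median 1.20 over 26, camera adjusted p = 3.12e-09, but adjusted p = 0.670 with an estimated correlation), as were complement genes (median 1.80 over 26, camera adjusted p = 0.000149, but adjusted p = 0.719 with an estimated correlation). Hepatocyte markers moved with complement, at a median of 2.61 with 11 of 15 higher in black skin (camera adjusted p = 0.161, and it passed without skin black 1 at 0.00123 or skin white 2 at 0.0397). Collagen genes were lower (median -1.39 over 21, camera adjusted p = 0.000111, but adjusted p = 0.719 with an estimated correlation), as were nerve and glia genes (median -1.49 over 9, camera adjusted p = 0.00151, but adjusted p = 0.670 with an estimated correlation). Smooth muscle markers moved with collagen, at a median of -1.28 with 8 of 10 lower (camera adjusted p = 0.014, but adjusted p = 0.719 with an estimated correlation), lost without skin black 1 (0.0979) or skin white 2 (0.235), and skeletal muscle markers had a median of -2.17 with 10 of 13 lower (camera adjusted p = 0.891), but 4.28 without skin white 2. Without that library collagen and nerve and glia genes had -0.69 and -0.76, and without skin black 2 complement and hepatocyte genes had 0.51 and 0.61. Melanin genes had -0.23 and pteridine genes -0.93 (camera adjusted p = 0.161 for both), and pteridine genes passed without skin white 1 (0.00556). Total counts in place of TMM moved the median log2 of all genes by 0.25 here, more than the size of the melanin median. Purine and carotenoid genes had -0.03 and -0.02 (camera adjusted p = 0.520 and 0.569). With assembled transcripts in place of symbol sums the melanin list passed (camera adjusted p = 0.028). Adjusted over the list alone, 34 ribosome, 5 interferon, 4 complement, 4 nerve and glia and 2 carotenoid genes passed, against 0 over all symbols.

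Single pigment gene values were PNP 3.38 ± 0.90 log2 (edgeR adjusted p = 0.213), PMEL -1.73 ± 0.48 (0.214), SLC45A2 -0.92 ± 0.31 (0.262), GCH1 -2.46 ± 0.87 (0.274), TYRP1 -1.18 ± 0.45 (0.293), XDH -1.75 ± 0.72 (0.317), MC1R -1.28 ± 0.57 (0.345) and TYR 0.80 ± 0.60 (0.554). Single libraries carried several of these, since PNP was 1.41 without skin black 3 (2330 CPM, against 192 and 280 in skin black 1 and 2), PMEL -0.99 without skin white 2, GCH1 and MC1R -1.30 and -0.70 without skin white 3, and TYR 0.44 without skin black 1 or 0.43 without skin white 3. With DESeq2, PNP (adjusted p = 0.00222), PMEL (0.0197) and GCH1 (0.0495) passed with these libraries in the fit, as did HPX (4.47e-10) and TLR2 (6.18e-05). Over transcripts edgeR passed 0 of 54612, with 4122 at unadjusted p under 0.05, and limma-voom passed 0 while limma-trend on FPKM passed up to 1 and DESeq2 1547. Without skin white 2, edgeR passed 1 transcript, again of RPL15. With symbol sums edgeR passed 0 of 11587, with 1699 at unadjusted p under 0.05. At 14.1% of transcripts the morphs did not overlap (chance 10%). Camera passed 7 of 30 lists, and at least as many in 7 of 10 splits of the same libraries, the real one included.

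Between red and black liver the lists with the smallest p held red cell and drug metabolism genes, both higher in red liver on average. CA2, the red cell carbonic anhydrase, had 138 ± 19.5 CPM in red and 44.4 ± 15.6 in black liver (SD, n = 3 per morph), EPB42 20.2 ± 8.12 and 5.58 ± 2.66, and the ammonium channel RHAG 18.6 ± 8.72 and 8.34 ± 1.25. CYP2K1, a monooxygenase, had 944 ± 261 and 415 ± 139, and POR, which passes electrons to such enzymes, 364 ± 152 and 160 ± 41.8. AHSG, a secreted plasma protein, had 3500 ± 3130 and 982 ± 1360, and the complement protease MASP1 320 ± 84.9 and 190 ± 61.9. DSG2, of desmosomes, had 21.7 ± 11.7 and 10.1 ± 3.69. Liver black 3 stood apart, with 156 CPM of ALB against 19300 to 103000 in the other livers, as did liver red 1, with 219 CPM of the egg coat gene ZP3 against at most 1.92.

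Erythrocyte genes were higher in red liver as a list (median log2 1.16 over 11, camera adjusted p = 5.29e-09, but adjusted p = 0.633 with an estimated correlation). Xenobiotic genes had 0.53 over 12 (camera adjusted p = 0.0051, but adjusted p = 0.664 with an estimated correlation), lost without liver black 3 (0.303). Keratinocyte genes had 0.54 over 14 (camera adjusted p = 0.0154, but adjusted p = 0.633 with an estimated correlation), lost without liver black 2 (0.114), liver black 3 (0.0986) or liver red 2 (0.128). Hepatocyte genes had 0.34 over 18 (camera adjusted p = 0.0155, but adjusted p = 0.633 with an estimated correlation), lost without liver black 3 (0.0986) or liver red 3 (0.154). Complement genes had 0.21 over 30 (camera adjusted p = 0.0467, but adjusted p = 0.808 with an estimated correlation), lost without liver black 2 (0.15), liver black 3 (0.44), liver red 3 (0.388) or liver white 2 (0.0529). Without liver black 1 the medians of complement, keratinocyte and xenobiotic genes were 0.43, 0.93 and 1.01, and with total counts in place of TMM those of hepatocyte and complement genes were 0.15 and 0.09. Camera passed 6 of 30 lists, but 2 without liver black 3, 10 without liver black 1 and 11 without liver red 1. Within lists, 4 of 11 erythrocyte genes passed adjusted over the list alone, against 0 over all symbols. Of 45169 transcripts edgeR passed 0, with 1944 at unadjusted p under 0.05, and limma-voom passed 0 while limma-trend on FPKM passed up to 5 and DESeq2 260. Without liver white 2, edgeR passed 1 transcript, of RPL15. For symbol sums the edgeR count was 0 of 10874, with 470 at unadjusted p under 0.05, and CA2 passed with DESeq2 (adjusted p = 0.0201). The 2 morphs did not overlap at 8.98% of transcripts (chance 10%).

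On average, red liver carried less transcript of cholesterol synthesis, respiratory chain and ribosome genes than white liver, and more of cell division and leukocyte genes. CYP51A1, a sterol demethylase, had 11.5 ± 6.22 CPM in red and 78.2 ± 40.9 in white liver (SD, n = 3 per morph), and IDI1, which makes the building block of sterols, 12.6 ± 4.42 and 76.2 ± 49.5. CCNB1, which drives entry into mitosis, had 12.4 ± 10.9 and 3.24 ± 0.696, and the mitotic kinase AURKB 16.5 ± 6.54 and 6.61 ± 1.22. PTPRC, the pan-leukocyte phosphatase, had 149 ± 19.2 and 62.7 ± 7.27, and LCK, a T cell kinase, 25.6 ± 11.1 and 9.70 ± 3.63. NDUFB5 of respiratory complex I had 32.1 ± 5.03 and 62.5 ± 20.0, and RPS19 1360 ± 520 and 2440 ± 865. White livers were not alike, since VTGA2, a yolk precursor made by the liver of egg-laying animals, had 1.44 CPM in liver white 1 but 39500 and 87700 in liver white 2 and 3. Liver red 1 stood apart among red livers, with ZP3 as given above. It had 24.8 CPM of CCNB1 against 4.25 and 8.16 in liver red 2 and 3.

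Cholesterol and bile genes were lower in red liver (median log2 -1.81 over 24, camera adjusted p = 6.32e-14, but adjusted p = 0.330 with an estimated correlation), as were oxidative phosphorylation genes (median -0.67 over 28, camera adjusted p = 1.37e-09, but adjusted p = 0.403 with an estimated correlation) and ribosome genes (median -0.61 over 34, camera adjusted p = 1.41e-09, but adjusted p = 0.403 with an estimated correlation). Proliferation genes were higher (median 1.10 over 26, camera adjusted p = 9.2e-12, but adjusted p = 0.403 with an estimated correlation), as were antigen presentation and leukocyte genes (median 0.96 over 22, camera adjusted p = 1.5e-09, but adjusted p = 0.217 with an estimated correlation). Hepatocyte markers had a median of -0.59 with 12 of 18 lower (camera adjusted p = 0.109), and passed without liver black 3 (0.029) or liver red 3 (0.0272). Interferon genes had 0.97 over 26 (camera adjusted p = 2.17e-05, but adjusted p = 0.403 with an estimated correlation). Collagen genes had -0.39 over 20 (camera adjusted p = 0.0224, but adjusted p = 0.445 with an estimated correlation), lost without liver red 1 (0.998), liver white 2 (0.193) or liver white 3 (0.075). Smooth muscle markers had -0.53 over 9 (camera adjusted p = 0.0224, but adjusted p = 0.425 with an estimated correlation), lost without liver red 1 (0.416), liver white 2 (0.193) or liver white 3 (0.0549). Erythrocyte genes had 0.57 over 11 (camera adjusted p = 0.0245, but adjusted p = 0.427 with an estimated correlation), lost without liver red 2 (0.31), liver white 1 (0.159) or liver white 3 (0.136). Without liver red 1 proliferation genes had 0.85 (camera adjusted p = 1.69e-08) and CCNB1 0.93 log2 in place of 1.94. Other medians moved by over 1.5 times without liver red 3 (interferon 0.27 and ribosome -0.39), liver red 2 (ribosome -0.92, collagen -0.86 and smooth muscle -1.16), liver white 1 (collagen -0.65) or liver white 2 (erythrocyte 1.03 and hepatocyte -0.13). With total counts in place of TMM the medians of oxidative phosphorylation, ribosome, hepatocyte, collagen and smooth muscle genes were -0.27, -0.24, -0.28, -0.04 and -0.11, and that of cholesterol and bile genes -1.39. Camera passed 18 of 30 lists, but 10 without liver white 3 and 11 without liver red 1. Adjusted over the list alone, 14 cholesterol and bile, 9 proliferation and 3 leukocyte genes passed, against 0 over all symbols. With edgeR, CYP51A1 had -2.77 ± 0.59 log2 and IDI1 -2.60 ± 0.55 (adjusted p = 0.345 for both), and IDI1 passed without liver white 1 (0.0372). PTPRC had 1.25 ± 0.28 (edgeR adjusted p = 0.345). With DESeq2 these passed (adjusted p = 0.00182, 0.00183 and 0.00218). Over transcripts edgeR passed 0 of 45169, with 2923 at unadjusted p under 0.05, and limma-voom passed 0 while limma-trend on FPKM passed up to 4 and DESeq2 361. With symbol sums edgeR passed 0 of 10874, with 1258 at unadjusted p under 0.05. At 13.2% of transcripts the morphs did not overlap (chance 10%).

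In black liver cholesterol synthesis genes were on average lower and proliferation genes higher than in white liver. The white livers were not alike. Liver white 2 and 3 had far more VTGA2 than liver white 1, as given above, and lower TMM factors (0.76 and 0.72 against 1.04). Liver black 1 carried VTGA2 too, as given below. No fit left out both liver white 2 and liver white 3, so the part they play together was not tested. IDI1 had 14.3 ± 3.37 CPM in black and 76.2 ± 49.5 in white liver (SD, n = 3 per morph), and PMVK, another enzyme of that pathway, 7.59 ± 2.22 and 29.6 ± 8.62. The replication helicase genes MCM4, MCM6 and MCM7 had 48.4 ± 17.7, 21.2 ± 6.61 and 36.6 ± 14.8 in black and 22.4 ± 1.66, 7.96 ± 1.82 and 13.7 ± 0.638 in white liver. ATP5PO, a subunit of ATP synthase, had 120 ± 9.16 and 266 ± 87.2, RPS7 1620 ± 528 and 3700 ± 1040, and the antiviral gene MX2 152 ± 133 and 29.5 ± 10.8 (2.37 log2, but 1.36 without liver black 1). TMEM45B, a membrane protein linked to cell growth, was the 1 symbol past the threshold and fell by 2.36 ± 0.26 log2 (SE) in black liver, with 7.03 ± 1.26 CPM in black and 36.2 ± 5.77 in white (edgeR adjusted p = 0.0378, chosen after values were seen).

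Hepatocyte markers were lower in black liver too (median log2 -1, 13 of 18 lower, camera adjusted p = 0.002, but adjusted p = 0.272 with an estimated correlation), and ALB was 156 CPM in liver black 3 against 19300 to 103000 in the other livers. The TMEM45B call was lost in edgeR without liver black 1 (adjusted p = 0.09), liver black 3 (0.196), liver red 1 (0.121), liver red 2 (0.0611), liver red 3 (0.147), liver white 2 (0.0763) or liver white 3 (0.189), and with only black and white in the fit (0.144). It held with DESeq2 (adjusted p = 2.13e-14). Cholesterol and bile genes were lower in black liver (median log2 -2.05 over 24, camera adjusted p = 1.96e-12, but adjusted p = 0.272 with an estimated correlation), as were ribosome genes (median -0.81 over 34, camera adjusted p = 7.97e-11, but adjusted p = 0.401 with an estimated correlation) and oxidative phosphorylation genes (median -0.64 over 28, camera adjusted p = 3.03e-08, but adjusted p = 0.401 with an estimated correlation). Proliferation genes were higher (median 1.27 over 26, camera adjusted p = 5.03e-11, but adjusted p = 0.401 with an estimated correlation), as were interferon genes (median 0.98 over 26, camera adjusted p = 1.73e-06, but adjusted p = 0.401 with an estimated correlation) and antigen presentation and leukocyte genes (median 0.71 over 22, 20 higher, camera adjusted p = 2.77e-05, but adjusted p = 0.272 with an estimated correlation). Collagen genes had -0.99 over 20 with 19 lower (camera adjusted p = 0.00105, but adjusted p = 0.426 with an estimated correlation), and erythrocyte genes -0.65 with 11 of 11 lower (camera adjusted p = 0.0182, but adjusted p = 0.426 with an estimated correlation), the latter lost without liver black 1 (0.0539), liver black 3 (0.154) or liver white 2 (0.205). Medians moved by over 1.5 times without liver white 2 (leukocyte 0.38 and hepatocyte -0.64) or liver black 2 (proliferation 0.79 and erythrocyte -1.04). With total counts in place of TMM the medians of oxidative phosphorylation, ribosome, hepatocyte, collagen and erythrocyte genes were -0.09, -0.28, -0.42, -0.44 and -0.16, and that of cholesterol and bile genes -1.48. Within lists, 17 cholesterol and bile, 21 proliferation and 5 leukocyte genes passed adjusted over the list alone, against 0 over all symbols. IDI1 had -2.41 ± 0.55 log2 (edgeR adjusted p = 0.146) and passed without liver white 1 (0.0274). With DESeq2 PMVK (adjusted p = 0.000993) and IDI1 (0.00129) passed. Of 45169 transcripts edgeR passed 0, with 4339 at unadjusted p under 0.05, and limma-voom passed 0 while limma-trend on FPKM passed up to 3 and DESeq2 737. Without liver white 2, edgeR passed 1 transcript, of RPL15. With symbol sums 2117 of 10874 had an unadjusted p under 0.05. The 2 morphs did not overlap at 16.3% of transcripts (chance 10%). Camera passed 16 of 30 lists.

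On average, red oviduct had more transcript of collagen and other matrix genes than black oviduct and less of cell division genes. FN1, the cell-binding matrix protein fibronectin, had 227 ± 160 CPM in red and 55.7 ± 21.6 in black oviduct (SD, n = 3 per morph), COL14A1 7.96 ± 2.27 and 0.757 ± 1.00, and POSTN, a matrix protein of growing tissue, 62.6 ± 8.41 and 13.4 ± 11.7. The mitotic cyclin CCNA2 had 4.65 ± 3.20 and 110 ± 173, NUSAP1, of the spindle, 3.76 ± 1.63 and 66.8 ± 96.3, and RRM2, which makes DNA precursors, 11.2 ± 2.90 and 123 ± 176. RPL10 had 3530 ± 1410 and 1580 ± 1110, and EGFL7, of vessel walls, 19.0 ± 13.4 and 6.51 ± 1.43. The library labelled oviduct black 3 stood apart, with 310 CPM of CCNA2 against 6.28 and 13.1 in oviduct black 1 and 2, and 5570 CPM of the egg coat gene ZP4 against at most 1.71 in every other oviduct library.

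Collagen genes were higher in red oviduct as a list (median log2 1.72 over 21, camera adjusted p = 1.36e-11, but adjusted p = 0.699 with an estimated correlation), as were ribosome genes (median 0.90 over 34, camera adjusted p = 4.43e-09, but adjusted p = 0.699 with an estimated correlation). Proliferation genes were lower (median -3.48 over 26, camera adjusted p = 4.43e-09, but adjusted p = 0.699 with an estimated correlation). Oviduct black 3 carried most of this, since the median without it was -0.65 (camera adjusted p = 0.000255), and in 6 of 26 all black libraries lay above all red. Collagen and ribosome genes without it had 1.20 and 0.40 (camera adjusted p = 1.21e-05 and 0.00787). Oocyte genes were lower for 5 of 5 with a median of -8.37 (camera adjusted p = 0.0804), and passed without oviduct black 1 (0.0323) but without oviduct black 3 had 0.17 (0.702). Vascular and adipose genes had 0.88 over 10 (camera adjusted p = 0.0203, but adjusted p = 0.699 with an estimated correlation), lost without oviduct black 2 (0.122), oviduct black 3 (0.102), oviduct red 1 (0.0907) or oviduct red 3 (0.0938). Other medians moved by over 1.5 times without oviduct red 1 (ribosome 0.57) or oviduct black 2 (collagen 2.64 and ribosome 1.43). Camera passed 4 of 30 lists, but 7 without oviduct white 1 and 8 without oviduct black 1 or oviduct red 3. Adjusted over the list alone, 25 of 26 proliferation and 5 of 5 oocyte genes passed, but 0 of either without oviduct black 3, against 0 over all symbols. With edgeR, FN1 had 2.03 ± 0.59 log2 and CCNA2 -4.56 ± 1.31 (adjusted p = 0.513 for both), but FN1 had 1.27 without oviduct red 1 and CCNA2 -1.07 without oviduct black 3. Over transcripts edgeR passed 0 of 58446, with 4141 at unadjusted p under 0.05, and limma-voom passed 0 while DESeq2 passed 345. For symbol sums the edgeR count was 0 of 11641, with 1055 at unadjusted p under 0.05. At 10.9% of transcripts the morphs did not overlap (chance 10%).

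On average and after TMM scaling, red oviduct had less transcript of cholesterol synthesis, respiratory chain, cell division and red cell genes than white oviduct. The sterol enzymes CYP51A1 and DHCR7 had 2.74 ± 0.694 and 5.75 ± 2.01 CPM in red and 90.6 ± 71.0 and 34.1 ± 16.4 in white oviduct (SD, n = 3 per morph). HSP90B1, a chaperone of the secretory pathway, had 281 ± 71.2 and 10500 ± 8970, and CRELD2, of the same compartment, 11.8 ± 5.26 and 842 ± 747. TOP2A, which untangles DNA in dividing cells, had 18.1 ± 6.23 and 61.0 ± 16.5, PCNA 36.5 ± 12.1 and 119 ± 50.6, and COX4I1 of the respiratory chain 87.3 ± 21.0 and 220 ± 61.0. CA2 had 24.6 ± 10.8 and 75.1 ± 19.1. GBP1, an interferon-induced GTPase, had 48.2 ± 40.6 and 11.3 ± 7.60. AGR2 had 131 CPM in oviduct white 1 but 56400 and 108000 in oviduct white 2 and 3.

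Cholesterol and bile genes were lower in red oviduct (median log2 -1.58 over 23, camera adjusted p = 9.16e-07, but adjusted p = 0.533 with an estimated correlation), as were proliferation genes (median -1.69 over 26, camera adjusted p = 9.05e-06, but adjusted p = 0.533 with an estimated correlation) and erythrocyte genes (median -1.48 over 10, camera adjusted p = 8.02e-05, but adjusted p = 0.533 with an estimated correlation). Oxidative phosphorylation genes had -0.61 over 28 (camera adjusted p = 1.75e-06, but adjusted p = 0.533 with an estimated correlation). With total counts in place of TMM the medians of oxidative phosphorylation, cholesterol and bile, proliferation and erythrocyte genes were -0.03, -0.90, -1.20 and -0.89, and those of ciliary and oviduct secretion genes, given below, -0.16 and -1.47. Total counts moved the median of all genes up by 0.7, so lists higher in red, given below, move up with them. Interferon genes had 0.57 over 26 (camera adjusted p = 0.000318, but adjusted p = 0.533 with an estimated correlation), lost without oviduct white 2 (0.0571). Ciliary genes were lower for 22 of 22 (median -1.13, camera adjusted p = 0.000327, but adjusted p = 0.533 with an estimated correlation), lost without oviduct red 1 (0.0683). Oviduct secretion genes were lower for 13 of 17 (median -2.22, camera adjusted p = 0.00878, but adjusted p = 0.533 with an estimated correlation), lost without oviduct white 2 (0.0527) or oviduct white 3 (0.06). Vascular and adipose genes had 1.78 over 10 (camera adjusted p = 0.00199, but adjusted p = 0.533 with an estimated correlation), and collagen genes 0.74 over 21 (camera adjusted p = 0.0115, but adjusted p = 0.561 with an estimated correlation), the latter lost without oviduct white 1 (0.417). Medians moved by over 1.5 times without oviduct red 2 (collagen 0.36 and erythrocyte -2.32), oviduct red 3 (interferon 0.24 and ciliary -2.70), oviduct white 1 (interferon 2.35 and secretion -3.44), oviduct white 2 (ciliary -0.73) or oviduct white 3 (interferon 0.30). Within lists, 10 of 23 cholesterol and bile, 8 of 17 oviduct secretion, 2 of 10 vascular and adipose and 1 of 21 collagen genes passed adjusted over the list alone, against 0 over all symbols. CYP51A1 had -5.03 ± 0.89 log2 and DHCR7 -2.56 ± 0.60 (edgeR adjusted p = 0.333 for both), and CYP51A1 passed without oviduct white 1 (0.0174). With DESeq2 CYP51A1 (adjusted p = 4.82e-07) and DHCR7 (0.00441) passed. Of 58446 transcripts edgeR passed 0, with 4340 at unadjusted p under 0.05, and limma-voom passed 0 while DESeq2 passed 940. Without oviduct white 1, edgeR passed 4 transcripts, of CRELD2, CALR, PDIA6 and HSP90B1, each higher in white and each acting in protein folding of the secretory pathway. With symbol sums edgeR passed 0 of 11641, with 1272 at unadjusted p under 0.05. The 2 morphs did not overlap at 14.9% of transcripts (chance 10%). Camera passed 14 of 30 lists.

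On average and after TMM scaling, black oviduct had less transcript of ribosome, respiratory chain, haemoglobin and cholesterol genes than white oviduct. RPLP0, of the ribosomal stalk, had 1630 ± 1060 CPM in black and 6450 ± 3380 in white oviduct (SD, n = 3 per morph). HBA and HBB, the globin chains, had 434 ± 298 and 238 ± 103 in black and 2770 ± 915 and 1370 ± 557 in white. COX5A of the respiratory chain had 148 ± 25.4 and 386 ± 100, and NDUFB10 56.7 ± 7.60 and 195 ± 106. CYP51A1 had 9.97 ± 6.12 and 90.6 ± 71.0. TIMP2, an inhibitor of matrix proteases, had 162 ± 191 and 6200 ± 6260, and COL1A1 78.9 ± 73.8 and 809 ± 746. Oviduct black 3 with its oocyte transcripts is among the 3 black libraries.

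As lists, ribosome genes were lower in black oviduct (median log2 -1.58 over 34, camera adjusted p = 6.11e-18, but adjusted p = 0.512 with an estimated correlation), as were oxidative phosphorylation genes (median -0.82 over 28, camera adjusted p = 1.9e-12, but adjusted p = 0.441 with an estimated correlation), erythrocyte genes (median -2.35 over 10, camera adjusted p = 3.24e-08, but adjusted p = 0.424 with an estimated correlation) and cholesterol and bile genes (median -1.35 over 23, camera adjusted p = 2.23e-05, but adjusted p = 0.505 with an estimated correlation). Collagen genes had -1.09 over 21 (camera adjusted p = 2.23e-05, but adjusted p = 0.580 with an estimated correlation), lost without oviduct black 3 (0.588). Without that library ribosome, oxidative phosphorylation, erythrocyte and cholesterol genes had medians of -1.07, -0.76, -1.95 and -1.46 (camera adjusted p = 1.97e-13, 2.61e-09, 9.5e-07 and 1.2e-06). Oocyte genes were higher in black oviduct for 5 of 5 with a median of 9.58 (camera adjusted p = 0.0986), but without oviduct black 3 had -0.65 (0.431). Oviduct secretion genes had -2.14 over 17 (camera adjusted p = 0.00142, but adjusted p = 0.580 with an estimated correlation), lost without oviduct black 3 (0.193). Ciliary genes had -0.65 over 22 (camera adjusted p = 0.0282, but adjusted p = 0.822 with an estimated correlation), lost without oviduct black 2 (0.15), oviduct black 3 (0.636), oviduct white 2 (0.424) or oviduct white 3 (0.213). With total counts in place of TMM the medians of ribosome and erythrocyte genes were -0.84 and -1.58 and that of secretion genes -1.21, but those of oxidative phosphorylation, cholesterol and bile, collagen and ciliary genes were 0.11, 0.09, -0.07 and 0.32, so the direction of these, apart from collagen, rests on the scaling. Medians also moved by over 1.5 times without oviduct white 3 (cholesterol and bile -0.42, collagen -0.52 and secretion -1.15), oviduct white 2 (collagen -0.71), oviduct white 1 (ciliary -1.10), oviduct black 1 (ciliary -1.67) or oviduct black 2 (collagen -1.75). Camera passed 13 of 30 lists, but 8 without oviduct white 3. Adjusted over the list alone, 2 of 23 cholesterol and bile and 4 of 5 oocyte genes passed, against 0 over all symbols. With edgeR, CYP51A1 had -3.18 ± 0.81 log2 (smallest adjusted p = 0.461 over all symbols), and it passed with DESeq2 (adjusted p = 0.0153), as did TIMP2 (0.0171). Over transcripts edgeR passed 0 of 58446, with 4403 at unadjusted p under 0.05, and limma-voom passed 0 while limma-trend on FPKM passed up to 1 and DESeq2 542. For symbol sums the edgeR count was 0 of 11641, with 1246 at unadjusted p under 0.05. At 9.55% of transcripts the morphs did not overlap (chance 10%).

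**Figure D2:**
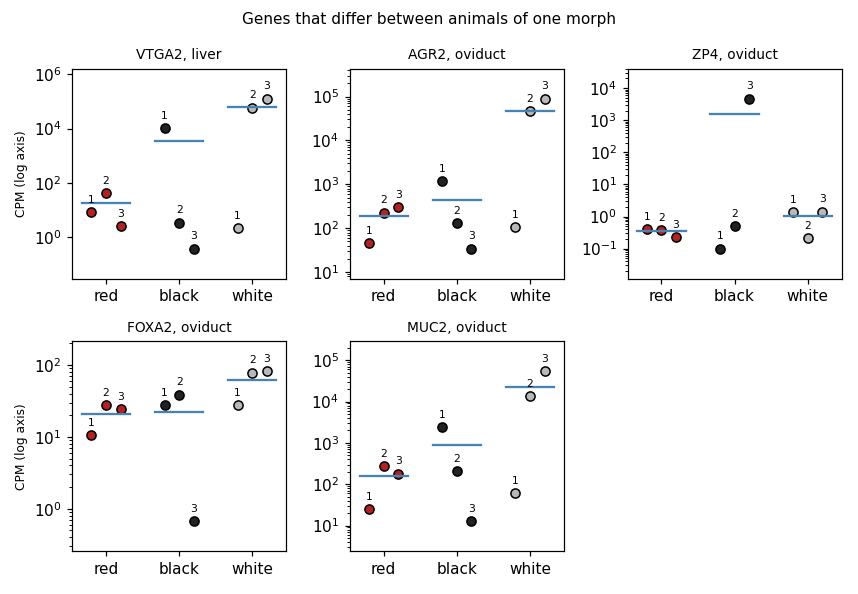
Liver and oviduct genes that differ between animals of 1 morph, with morph on the horizontal axis and CPM (TMM-scaled over all 27 libraries, log axis) on the vertical axis. Each point is a library numbered by replicate and drawn no lower than 0.1 CPM, and the blue line is the mean of 3.

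Tested for any difference among the 3 morphs, edgeR passed 0 transcripts in skin, liver and oviduct, with 3000, 3050 and 4801 at unadjusted p under 0.05 and smallest adjusted p = 0.778, 0.713 and 0.574. DESeq2 passed 1248, 475 and 480, limma-trend on FPKM up to 2, 6 and 1, and limma-voom 0 in each tissue. Without oviduct white 1, edgeR passed 13 transcripts in oviduct.

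Whether morphs differed by tissue was tested with all libraries. For black against white 2 symbols passed: EHHADH, a peroxisomal enzyme of fatty acid oxidation, and HNRNPH1, a splicing regulator, each chosen after values were seen. EHHADH had 8.75, 14.1 and 15.2 CPM in black liver and 54.5, 124 and 111 in white liver, against 1.73 to 2.48 in black and 2.76 to 4.81 in white skin (log2 -2.93 in liver, -0.81 in skin and 0.76 in oviduct, edgeR adjusted p = 0.047 for the difference among tissues, and 0.159 with each animal as a replicate block). HNRNPH1 had 50.3, 59.7 and 60.6 CPM in black and 186, 313 and 191 in white oviduct (log2 -2.02 in oviduct, 0.34 in liver and 0.05 in skin, edgeR adjusted p = 0.0185). Over transcripts edgeR passed 0 of 76309 for red against black, red against white and black against white, with 3253, 2704 and 3453 at unadjusted p under 0.05, and DESeq2 passed 43, 134 and 162. With symbol sums edgeR passed 0, 0 and 2 of 12516, with 1144, 966 and 1350 at unadjusted p under 0.05, and DESeq2 passed 58, 141 and 206. Single oviduct libraries moved these counts most: without oviduct white 1 edgeR passed 172 symbols for black against white and 331 for red against white, and without oviduct black 2 it passed 24 for black against white, 102 for red against black and 1 for red against white. For red against white it also passed 2 without oviduct black 3 and 1 without oviduct red 2. For black against white it passed 0 without oviduct black 3, oviduct white 2 or liver white 2, 4 without oviduct black 1 and 5 without liver white 1. It passed 1, of HNRNPH1, without any of oviduct red 1 or 3, skin red 1, 2 or 3, liver red 2 or 3, skin black 1, 2 or 3, liver black 1, 2 or 3, oviduct white 3, skin white 2 or 3, or liver white 3.

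**Figure D3:**
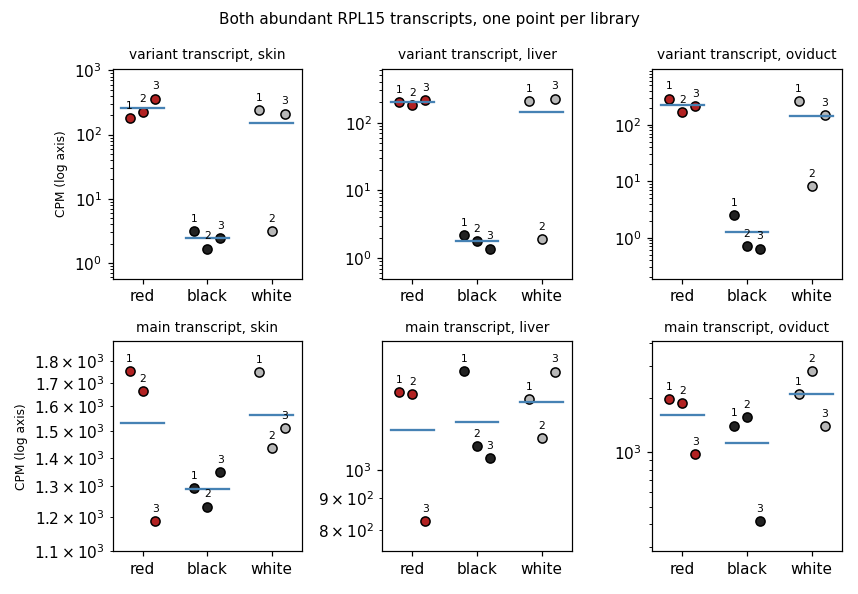
Both abundant RPL15 transcripts in each tissue, with morph on the horizontal axis and CPM over total counts (log axis) on the vertical axis. Each point is a library numbered by replicate, and the blue line is the mean of 3.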

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

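The list tests between tissues with an estimated correlation, the test for ovarian tissue, all tests of depth, the test of colour morph alone and all tests of other splits of the libraries were chosen after the result was seen, while the other tests of the first 2 patterns below were written before their values were computed.

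A difference between tissues in how 2 morphs compare raised 9 results. The difference of red over black was lower in skin than in liver for complement and acute phase genes (camera adjusted p = 0.038 with an estimated correlation, 4.53e-16 with the preset one, 0.0537 with each animal as a replicate block), and the call was lost on leaving out 17 of 27 libraries (range 0.0118 to 0.299). Hepatocyte genes did likewise (camera adjusted p = 0.038 with an estimated correlation, 8.71e-09 with the preset one), with 19 of 27 omissions losing the call (range 0.000441 to 0.299). For pteridine genes the red over black difference was higher in skin than in liver (camera adjusted p = 0.0284 estimated, 0.000181 preset). Of 27 omissions 8 lost the call (range 0.00411 to 0.0969). The difference of black over white was higher in skin than in liver for cholesterol and bile genes (camera adjusted p = 0.0261 with an estimated correlation, 2.24e-18 with the preset one) and fatty acid genes (0.0228 and 4.41e-09), and both calls were lost only without oviduct black 3 (0.0562 for both) or skin black 3 (0.0704 and 0.0641). In the same direction, carotenoid genes (camera adjusted p = 0.0279 with an estimated correlation, 0.00065 with the preset one, 0.105 with the replicate block) lost the call in 5 of 27 omissions. Hepatocyte genes for black over white (camera adjusted p = 0.0312, 2.02e-08 and 0.0635 in the same order) lost it in 12 and xenobiotic genes (0.0279, 0.000796 and 0.151) in 11. In all, 81 of 270 such tests passed with the preset correlation and 8 with an estimated one. Liver white 2 and 3, high in VTGA2, were never left out together, so their joint part in calls against white was not tested.

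The last of the 9 was the count of 2 symbols that differed by tissue between black and white. HNRNPH1 (edgeR adjusted p = 0.0185) lost its call without oviduct black 3 (0.053), oviduct white 2 (0.125) or liver white 2 (0.0579) and had 0.0477 with the replicate block. EHHADH (edgeR adjusted p = 0.047) lost its call in 21 of 27 omissions (range 0.0052 to 0.181).

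The first pattern weighed is that of assembled transcripts nearly absent in some animals and abundant in others. An RPL15 transcript (TRINITY_DN15607_c0_g1_i16_5) had 151 to 364 CPM in every red animal, white 1 and white 3, and at most 8.19 in every black animal and white 2, in each of 3 tissues, while the most abundant RPL15 transcript had 415 to 2790 CPM throughout. Among 67 such transcripts, 91.0% had the same pattern of absence in 3 tissues, against at most 1.5% in 100 shuffles of animals between tissues, which is consistent with sequence variants carried by the animal and assembled apart. The RPL15 pattern had been seen before this test was written. A change in expression of the whole gene could be tested only for the 10 of 67 transcripts whose symbol had other transcripts. For these it was not borne out, since the median log2 range of the symbol sum over skin libraries was 0.89 against 8.02 for the transcript. For the rest it was not tested.

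The second pattern is the library labelled oviduct black 3. All 8 oocyte genes found were highest in it among oviduct libraries (ZP4 4720, ZP3 4480, ZP2 887, GDF9 220 and NPM2 176 CPM), and FOXA2, FOXJ1 and ESR1 were low at 0.667, 1.68 and 1.5 CPM, which is consistent with ovarian tissue in the piece. A library of another animal was not borne out, since 96.4% of 140 variant transcripts matched the skin and liver of black 3 and at most 60% those of another animal, although its low correlation with skin and liver had been seen before that test. Lower depth was not borne out either, at 23.5 M counts, inside the range of the other oviduct libraries. The labels give it as oviduct, and no other explanation was tested.

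The third pattern lies within white animals, with CPM here and in the second pattern scaled over all 27 libraries. VTGA2 in liver had 59600 and 128000 CPM in white 2 and 3 but 2.13 in white 1, and 10100 in black 1, and in oviduct AGR2 had 47200 and 89900, FCGBP 43400 and 90900 and MUC2 13400 and 53800 CPM in white 2 and 3 against 108, 29.5 and 61.0 in white 1. Colour morph alone does not give a difference within 1 morph, and white 1 at 2.13 CPM lay below black 1. The pattern was picked for its low white 1, so this restates it and is not a separate test. A difference in depth was not borne out, since 2 of the 4 libraries had totals inside the range of the others of their tissue. A difference in reproductive stage between animals could account for both gene groups, but stage is not given in the sources used here and was not tested.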

How the results depend on the processing

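The newer quasi-likelihood form, the fit without 2 doubted oviduct libraries and the list medians with total counts in place of TMM were chosen after the result was seen, as were the tests of other splits given here. The counts of 0 for the 9 morph pairs and 3 tests of any morph held with RLE scaling and limma-voom. They also held with no count filter, a filter of 1 CPM or the replicate block. The 9 pairs also held with 2 morphs only. A 2-fold threshold could only give 0, since it was applied to the transcripts that had passed. In oviduct the counts held without the libraries with the S suffix, oviduct red 1 and oviduct black 1. Liver has no such library. Without skin black 1 and 2, which carry the suffix, skin black keeps 1 library, so no count is given. In skin only black libraries carry it, so what it marks cannot be fully told apart from morph there. Lists and named genes were not refitted without all of these libraries. DESeq2 passed 938, 400 and 1547 transcripts in skin for red against black, red against white and black against white and 1248 for any morph, 260, 361, 737 and 475 in liver, and 345, 940, 542 and 480 in oviduct, and by tissue 43, 134 and 162, or 58, 141 and 206 with symbol sums. In the simulation of red against black most DESeq2 calls on transcripts were false, as given with the processing, while most on symbol sums were not. With limma-trend on log2(FPKM + 0.1), 3 passed for red against black, 1 for black against white and 2 for any morph in skin, and 5, 3 and 3 in liver. With limma-trend on log2(FPKM + 1), 4, 4, 3 and 6 passed in liver for the 3 pairs and any morph, and 1 for black against white and 1 for any morph in oviduct. The cause was not tested. Symbol sums gave 1 for black against white in liver (TMEM45B).

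With an estimated correlation 0 lists passed in each of the 9 pairs. For red against black in oviduct, 11 lists passed with assembled transcripts in place of symbol sums. Directions reversed for pteridine genes with assembled transcripts (camera adjusted p = 0.603) and purine genes with the replicate block (camera adjusted p = 0.84), both red against white in skin, for skeletal muscle genes between black and white skin with the replicate block (camera adjusted p = 0.147) and between red and black skin with assembled transcripts (0.801) and with the replicate block (0.484), and for BCO2 between red and black skin (-0.0014 log2 with DESeq2 and -0.0019 with RLE). Over named genes, other settings left 742 fold changes on the same side of the threshold, 51 stronger (all with DESeq2), 3 weaker and 2 reversed. Over lists they left 157 the same, 72 weaker, 6 stronger and 5 reversed. DESeq2 gave no adjusted p for PMEL between tissues.

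Leaving out each library in turn gave 0 to 1 transcripts for red against black and for black against white in skin and in liver, 0 to 4 for red against white and 0 to 13 for any morph in oviduct. By tissue, symbol sums gave 0 to 102, 0 to 331 and 0 to 172 for red against black, red against white and black against white. List counts ranged from 2 to 11 for red against black and 10 to 20 for red against white in liver, and from 4 to 8 for red against black and 8 to 15 for black against white in oviduct. Lists that could turn in direction were, for red against white in skin, carotenoid (camera adjusted p from 0.353 to 0.892, without skin white 1), pteridine (0.0271 to 0.818) and purine (0.353 to 0.996), and for black against white in skin, skeletal muscle (0.214 to 0.905), which also turned for red against black (0.11 to 0.989). Collagen genes for red against white in liver (0.000202 to 0.998) turned without liver red 1, and oocyte genes in oviduct for red against black (0.0323 to 0.702) and black against white (0.05 to 0.431) turned without oviduct black 3. Oocyte genes passed with the replicate block for both (9.6e-05 and 0.00229), and for red against black with assembled transcripts (0.0348). Genes whose log2 fold change turned sign were BCO2 (-0.11 to 0.28), MITF (-0.37 to 0.57) and PNP (-2.46 to 0.0029) for red against black skin, MC1R (-0.89 to 0.07), OCA2 (-0.39 to 1.14), PMEL (-0.74 to 0.41), TYR (-0.87 to 0.08), TYRP1 (-0.48 to 0.26) and XDH (-0.25 to 0.81) for red against white skin, and DCT (-1.33 to 3.72) and KIT (-0.28 to 0.26) for black against white skin. Between tissues they were AP3D1 for skin against liver (-0.11 to 0.21) and PMEL for liver against oviduct (-5.41 to 1.16).

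With replicate number as a block, 0 transcripts passed in each morph comparison, and lists numbered 16, 9 and 9 in skin, 7, 18 and 17 in liver and 7, 16 and 14 in oviduct. TMEM45B then had an edgeR adjusted p = 0.108, and hepatocyte genes in skin had camera adjusted p = 2.81e-05 for red against black and 0.00146 for black against white. Across morphs the pairs share only a number, as given above. With each animal as a block the tissue pairs gave 15608, 13179 and 20166 transcripts, the call for KRT5 between liver and oviduct was lost (edgeR adjusted p = 0.067), and besides the calls named with their results no other call changed.

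Other groupings of the same libraries were compared by count. For each of the 9 morph pairs, all 10 splits gave at least the 0 transcripts observed (highest other 1), as did 40 of 40 for any morph in each tissue (highest other 3) and all 10 draws for the 3 tests by tissue. No grouping can give fewer than 0, so these comparisons say nothing about chance. For black against white by tissue 1 draw gave 219 and another 2, and the cause was not tested. For the tissue pairs 1 of 21 splits was as large, the real one, with at most 591 in the others. For lists, of 10 splits each, as many lists passed in 4, 7 and 7 in skin, 5, 1 and 1 in liver and 10, 2 and 2 in oviduct, and only in liver against white did the real grouping exceed every other (at most 13), with too few splits to tell. Depth limited oviduct red 1, at 12.65 M counts, most.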

Other observations

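No test was run for the values in this part, which were chosen after the result was seen. Several libraries carried transcripts annotated to parasites. Of 329 assembled transcripts whose NR hit was a nematode, oviduct black 2 had 70585 counts and skin red 1 had 29395, while the other libraries had at most 803. Of 92 annotated to kinetoplastids, which include the blood parasites of frogs, oviduct red 3 had 6585 counts and the others at most 133.

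Some genes of 1 tissue appeared in single libraries of another (CPM scaled over all 27 libraries). Liver red 1 had 332 CPM of ZP4, 318 of ZP3 and 23.3 of PMEL, against at most 5.68, 2.85 and 0.679 in the other livers. Oviduct black 3 had 357 CPM of PMEL and 373 of CCNB1, a mitotic cyclin, against at most 8.77 and 17.4 in the other oviducts. ALB had 233 CPM in liver black 3 and 27900 to 150000 in the other livers. In oviduct, TYR had 4590 and 6240 CPM in white 2 and 3 and 1670 in black 1, against at most 446 in the others, and XBP1, which drives the secretory response of gland cells, had 647 and 1170 in white 2 and 3 against at most 405 elsewhere.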
